A study of Rattus norvegicus with 20 samples.

How the data were processed

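The series measured gene expression by microarray in the ventral hippocampus of male rats aged 2 months, per the labels. A synthetic mimic of miR-17-5p (200 pmol in 1.5 µl) or a scrambled small RNA was injected into the ventral hippocampus, with 11 to 13 animals per condition. RNA came from the whole homogenate and from synaptoneurosomes, a fraction enriched in pinched-off synaptic endings, and 100 ng of total RNA was amplified and labelled. The 20 arrays form 4 groups of 5: homogenate control, homogenate mimic, synaptoneurosome control and synaptoneurosome mimic. Groups and replicate numbers were taken from the sample titles. The labels do not say that the 5 arrays of a group came from separate animals, so the p-values measure only the spread between these samples.

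The deposited table held log2 expression values from the authors, 1 column per array and 1 line per probe set. The values were made with RMA and Transcriptome Analysis Console, per the submitters' processing notes; their versions and settings are not given in the sources used here. RMA corrects background, equalises the distributions of arrays and sums probes on the log2 scale, which compresses changes of dim transcripts. The table held 68842 probe sets, no missing value and no column without a sample, with values from 2.11 to 19.93 and array medians from 5.11 to 5.26. The values were used as deposited. The number of arrays limits the precision of every comparison. No arrays were duplicates: the smallest mean absolute log2 difference between replicates of a group was 0.15.

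Gene names came from the platform annotation, which can be old. It gave exactly 1 gene symbol for 23446 probe sets, several symbols for 505, and left 44891 unnamed here. Gene numbers matched 22077 probe sets to a current gene table, which updated 1 symbol. Probe sets with 1 symbol covered 22093 genes. The probe set with the highest mean over the 20 arrays stood for its gene, and genes in the lowest 30% by mean (below a log2 value of 4.97) were left out, which left 15465 genes. Where probe sets of a named gene disagreed, the text says so. The precursor gene Mir17 was among the genes left out by this filter.

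Comparisons used limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups, 16 residual degrees of freedom, empirical Bayes moderation with a constant prior (2.56 prior degrees of freedom) and Benjamini-Hochberg adjustment over all tested genes. Genes with an adjusted p below 0.05 were said to change, rise or fall. The comparisons were mimic against control in each fraction, synaptoneurosome against homogenate in each treatment, and the difference of the mimic effect between fractions. Errors after ± are standard errors from limma for 5 against 5 arrays, or for all 4 groups where the difference of the mimic effect between fractions is given. Their spread is estimated from the 4 groups together, and arrays varied more in synaptoneurosomes than in homogenate. Errors and p-values in homogenate therefore also carry the spread of synaptoneurosomes. Those for mimic against control in synaptoneurosomes carry the smaller spread of homogenate and can be too small. Equal errors in both fractions do not mean equal precision. All limma and camera tests are two-sided. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and plots.

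The groups, the tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. There were 33 lists, 17 of pathways and 16 of cell types. The pathway lists covered described targets of the miR-17 family, the glutamatergic postsynapse, presynaptic vesicles, the GABAergic synapse, dendritically localised mRNAs, ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, the interferon response, innate inflammation, reactive astrocytes, stress and glucocorticoid response, neuromodulator receptors, immediate early genes, the microRNA machinery, the cell cycle and nuclear RNAs. The cell type lists covered excitatory neurons, dentate granule cells, CA1 pyramidal cells, CA3 and CA2 pyramidal cells, interneurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, infiltrating leukocytes, endothelium, mural cells with fibroblasts, choroid plexus, ependyma, blood and neurons from outside the hippocampus. A list needed 5 tested members, and 31 lists were tested. Mitochondrially encoded transcripts and nuclear RNAs had fewer tested members and were left out.

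Lists were tested with camera in limma, which sets a list against all other genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 31 lists of a comparison. With a correlation estimated from the data, no list passed in any of the 5 comparisons, and that p is given beside each call. A test chosen after seeing the data took, for each array, the mean of a list minus the mean of all other tested genes and compared groups with a two-sided exact permutation test (252 permutations, smallest possible p = 0.00794), adjusted over the lists. It shuffles all 10 arrays compared and leaves pairs out of account; between fractions, a test that flips signs within 5 pairs could not give a p below 0.0625, so no list could pass it. A test of seed sites in 3′ untranslated regions was planned, but sequences of those regions were not used here, and the list of described miR-17 targets stood in for it.

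The rule for named genes took the 12 largest rises and the 12 largest falls past the threshold in a comparison, or the 5 smallest unadjusted p in a direction where fewer than 5 passed, and up to 4 members of each list with the largest moderated statistic. It passed over symbols of predicted or olfactory receptor genes: 1 among the falls with the mimic in homogenate, 3 among the rises of the difference between fractions, and 0 elsewhere. For a gene named in one fraction comparison, the value in the other is given beside it. Genes outside the rule are said to have been chosen after their values were seen.

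The fits were tested on simulated data for all 15465 genes, with the spread of the real arrays, 200 changed genes and 10 draws. In the comparison of mimic with control in homogenate, 63% of genes changed 1.5-fold, 85.2% of those changed 2-fold and 99% of those changed 4-fold were recovered. The same shares were 60.4%, 88.6% and 98.8% for mimic against control in synaptoneurosomes. For synaptoneurosome against homogenate they were 59.2%, 87.4% and 99.4% in control rats and 64%, 86.8% and 99.4% in mimic rats. For the difference of the mimic effect between fractions they were 41.4%, 74% and 95.4%. Of genes changed by the smallest simulated log2 difference, 0.32, the shares recovered were 22.2% and 28.4% for mimic against control in homogenate and in synaptoneurosomes, 19.8% and 19.6% between fractions in control and mimic rats, and 8% for the difference between fractions. The median number of false calls was 1 for mimic against control in homogenate, 4.5 in synaptoneurosomes and 4.5 for the difference between fractions, and 0 in both fraction comparisons. With 200 genes changed at once, the Benjamini-Hochberg cut is looser than where few genes change. These shares can therefore overstate the recovery of a lone change. The deviations of arrays were reassigned at random within a fraction. A draw could thus place the 3 synaptoneurosome arrays that stood apart, described below, in 1 treatment group, unlike the real arrays. Such draws can add false calls that a median hides and can loosen the cut. Recovery in synaptoneurosomes and for the difference between fractions may be overstated for this reason too.

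Replicate numbers are shared by all groups, and the labels do not say what a number stands for. Whether equal numbers mark paired samples was tested by correlating, across genes, the deviations of arrays from their group means. Between fractions of a treatment, the 5 pairs with equal numbers had r from 0.241 to 0.476 in control rats and from 0.102 to 0.354 in mimic rats, and every array correlated best with its own number. The main fits and list tests take the arrays as unpaired. On the basis of these correlations, fits with the replicate number as a block were set beside them. They are given for lists where they change a call or move a count by over 1.5 times. For members of lists the block was fixed, on the arrays compared. For genes examined by name only the totals are given. The correlations are across genes, which are not independent replicates.

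The alternatives were: other filters, other scalings, an intensity trend with a robust prior, array weights, fits to 10 arrays, replicate blocks, the mean of a gene's probe sets, all probe sets, and leaving out each array in turn. An unadjusted p with a minimum fold, an estimated correlation for lists, leaving out 3 synaptoneurosome arrays that stood apart and the test of scores per array were also tried, the last pair being chosen after seeing the data.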

Results

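Gene expression was measured on 20 arrays of the rat ventral hippocampus, a region tied to emotional behaviour, after injection of a miR-17-5p mimic or a scrambled RNA. Each of the 4 groups (2 fractions by 2 treatments) held 5 arrays. The comparisons of mimic with control ask which transcripts differ when a mimic of this microRNA is supplied, and whether they do so in whole tissue or in the synaptic fraction. Comparing the fractions shows which transcripts are enriched in or depleted from synaptoneurosomes.

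Arrays of a homogenate group resembled one another closely, with pairwise r across genes from 0.9937 to 0.9966 in control rats and from 0.9934 to 0.998 in mimic rats. Synaptoneurosome arrays were more varied, from 0.9681 to 0.993 in control rats and from 0.9712 to 0.9965 in mimic rats. The median SD of a gene was 0.12 and 0.11 in the homogenate groups, 0.21 in synaptoneurosome control and 0.17 in synaptoneurosome mimic. Synaptoneurosome control 4, control 5 and mimic 5 stood apart from the other synaptoneurosome arrays, and 2 of these arrays lay in the control group and 1 in the mimic group. They had the highest scores (30.2, 45.1 and 53) on a component that held 52.2% of the variance within groups. The other arrays scored from -29.4 to 5.6.

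**Figure D1:**
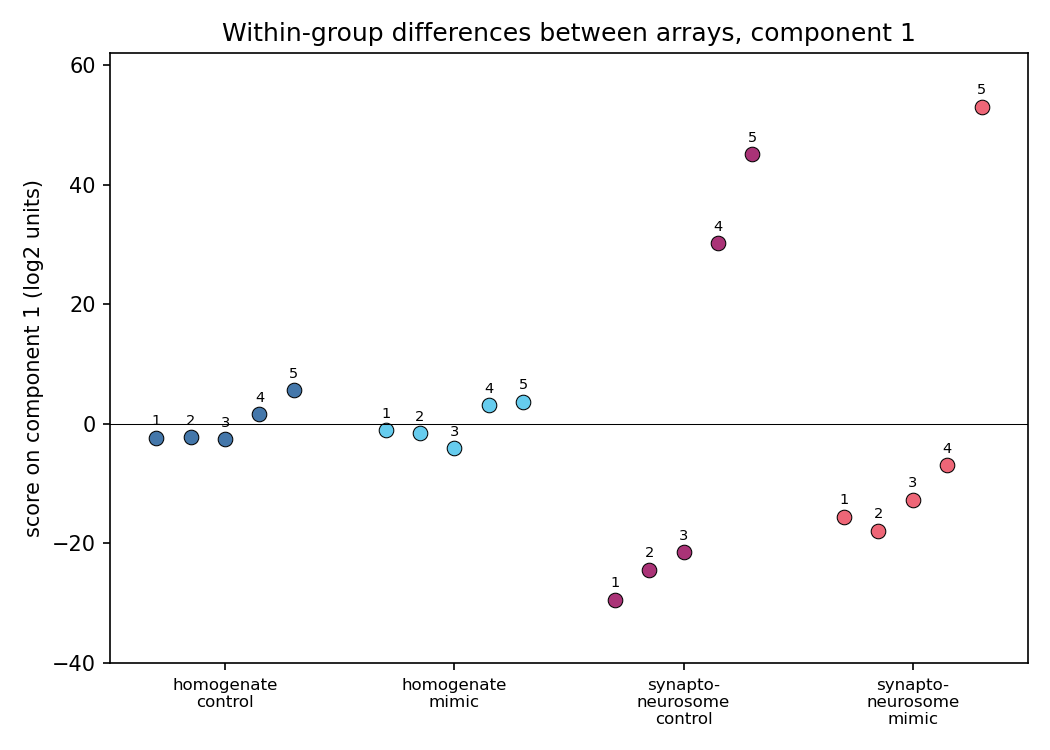
Score of each array (points, labelled with replicate numbers) on the first principal component of the differences within groups, in log2 units, for the 4 groups of 5 arrays. Synaptoneurosome control 4, control 5 and mimic 5 lie at 30.2, 45.1 and 53, and the other arrays lie between -29.4 and 5.6.

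In homogenate, the mimic was compared with the scrambled control to ask which transcripts of the whole tissue differed, and no gene passed the test. The genes with the smallest unadjusted p were Dlat, a subunit of the pyruvate dehydrogenase complex, with a log2 difference of 0.27 ± 0.07, and Rxrg, a retinoid X receptor, with 0.44 ± 0.12. On the lower side stood Il12rb2, an interleukin 12 receptor chain (-0.15 ± 0.05), and Btg1c (-0.24 ± 0.08). Their limma adjusted p was 1. In synaptoneurosomes the same differences were 0.06 ± 0.07 for Dlat, 0.23 ± 0.12 for Rxrg, 0.02 ± 0.05 for Il12rb2 and 0.02 ± 0.08 for Btg1c. The serotonin receptor Htr2c had a difference of 0.83 ± 0.27 in homogenate and 0.62 ± 0.27 in synaptoneurosomes. The galanin receptor Galr1 had 1.24 ± 0.52 and 1.11 ± 0.52, and neither receptor passed in either fraction (adjusted p = 1 in homogenate and 0.933 in synaptoneurosomes).

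Described targets of the miR-17 family, the transcripts that a mimic would be predicted to lower, were not detectably lower in homogenate. Of 58 tested targets 0 passed, and 0 when adjusted over the list alone. The list's score, its mean less that of other genes, was 1.77 in both groups (SD 0.03 in control and 0.02 in mimic), a difference of -0.01 (exact permutation test, p = 0.627). Members with the largest statistics had values above control: Nr4a3, an immediate early nuclear receptor (0.38 ± 0.11), Atg7, an autophagy enzyme (0.18 ± 0.07), and Ccnd2, a cyclin (0.29 ± 0.16). None of the 3 passed (limma adjusted p = 1). The differences in synaptoneurosomes were 0.26 ± 0.11 for Nr4a3, 0.13 ± 0.07 for Atg7 and 0.23 ± 0.16 for Ccnd2.

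**Figure D2:**
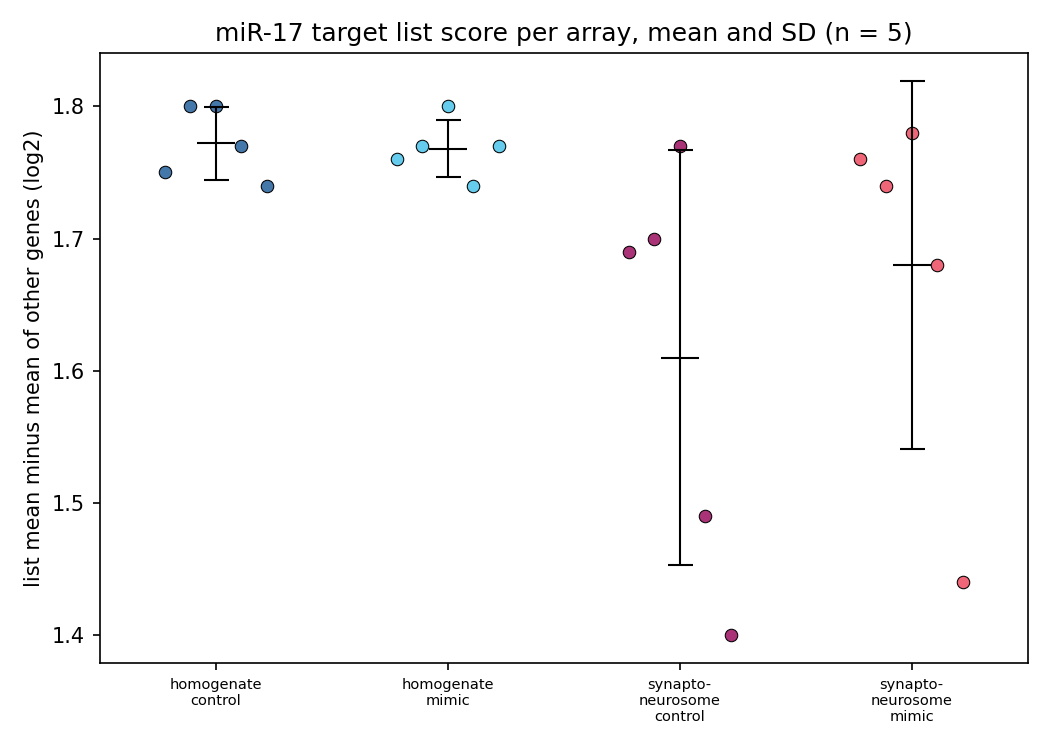
Mean log2 value of described miR-17 targets minus that of all other tested genes, for each array (points) with group mean and SD (bars, 5 arrays per group). The homogenate groups both average 1.77, and the means of the synaptoneurosome groups differ by 0.07 with wide overlap.

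Of the 31 lists, camera placed 6 apart from the other genes in homogenate, while 0 members of any of them passed, over all genes or adjusted over the list alone. Oxidative phosphorylation genes lay above other genes (median 0.11, adjusted p = 0.0017), with Ndufa5 of complex I at 0.15 ± 0.09 and Cox6a1 of complex IV at 0.48 ± 0.38. Microglial markers lay above other genes (median 0.23, adjusted p = 0.00215), with the lysosomal Cd68 at 0.30 ± 0.20, Aif1 at 0.11 ± 0.07 and Tyrobp at 0.16 ± 0.12. Markers of mural cells and fibroblasts lay below (median -0.16, adjusted p = 0.0017). For these 3 lists the adjusted p = 0.993 with an estimated correlation. Interferon response genes (median -0.04, adjusted p = 0.0209) also lay below, with an adjusted p = 0.993 with an estimated correlation. Leukocyte markers (median -0.04, adjusted p = 0.0265) had an adjusted p = 0.764 with an estimated correlation. Markers of neurons from outside the hippocampus (median -0.12, adjusted p = 0.0265) had an adjusted p = 0.565 with an estimated correlation. The spread of the mural score lay in the control arrays (SD 0.45 against 0.04 in mimic): homogenate control 2 and control 5 scored -0.17 and -0.40, the lowest control scored -1.15 and the mimic mean was -0.96. Homogenate mimic 4 had a microglial score of 0.13 against -0.30 to -0.24 in the other mimic arrays. Homogenate control 2 had a score of 0.09 for extrahippocampal neurons against -0.52 to -0.37. With no filter on dim genes the adjusted p was 0.122 for interferon genes and 0.0959 for extrahippocampal markers, and without the 3 synaptoneurosome arrays that stood apart it was 0.0541 for leukocyte markers.

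The count of 0 genes came from limma with all 20 arrays, where 268 genes had an unadjusted p below 0.05. A share of 0.05 of the tested genes is 773, but random regroupings of the 10 homogenate arrays gave a median of 228, so 268 is not below chance. With the 10 homogenate arrays alone, an intensity trend, array weights or replicate blocks the count of genes that passed was also 0. No list passed the exact test of scores per array (smallest adjusted p = 0.369).

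In synaptoneurosomes, the comparison asked whether the mimic altered transcripts close to synapses, and again no gene passed. The smallest unadjusted p belonged to Mir299, a microRNA precursor of an imprinted cluster, at 0.51 ± 0.10, and next to it stood Vasn, a membrane protein that binds TGF-beta, at 0.26 ± 0.06. On the lower side were the pseudogene Hspd1-ps5 (-0.38 ± 0.08) and Nrg2, a neuregulin (-0.20 ± 0.05). All 4 had a limma adjusted p = 0.933. Their differences in homogenate were 0.12 ± 0.10, 0.00 ± 0.06, -0.03 ± 0.08 and -0.11 ± 0.05. Adjusted over the list alone, 1 immediate early gene rose, Fosl2, an AP-1 subunit (0.58 ± 0.16), and 1 dentate granule marker fell, Stxbp6 (-0.26 ± 0.07). Over all genes 0 members of either list passed. The homogenate difference was 0.30 ± 0.16 for Fosl2 and -0.21 ± 0.07 for Stxbp6. The other probe set of Stxbp6 went the other way in both fractions (0.09 in synaptoneurosomes and 0.08 in homogenate).

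The described miR-17 targets lay slightly above the other genes in synaptoneurosomes by camera (median 0.04, adjusted p = 0.042), with an adjusted p = 0.869 with an estimated correlation. Their score differed by 0.07 (exact permutation test, p = 0.429), and 0 of 58 passed, as did 0 adjusted over the list alone. Ezh1, a histone methyltransferase, had the largest statistic among them, at 0.32 ± 0.11 here and 0.19 ± 0.11 in homogenate. Without the 3 arrays that stood apart, the adjusted p of the list was 0.669, and with no filter on dim genes it was 0.0685.

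Camera placed 6 further lists apart from other genes in synaptoneurosomes. Below other genes lay oxidative phosphorylation (median -0.17, adjusted p = 1.51e-07), with Cox4i1 at -0.37 ± 0.16 and Ndufa3 at -0.27 ± 0.10. Genes of the GABAergic synapse lay below (median -0.25, adjusted p = 0.00421), with the receptor subunits Gabrg1 at -0.31 ± 0.14, Gabrd at -0.53 ± 0.23 and Gabrb2 at -0.56 ± 0.29. Markers of mural cells and fibroblasts (median -0.24, adjusted p = 0.00115), with Vtn at -0.89 ± 0.42 and Col1a1 at -0.51 ± 0.26, and ribosomal proteins (median -0.10, adjusted p = 0.0425) were also below. Mural scores were high in control 2 and control 5 here too (-0.64 and -0.62), against -1.50 to -1.37 in the other controls and -1.59 to -1.24 in the mimic arrays. Above other genes lay the microRNA machinery (median 0.09, adjusted p = 0.0425) and choroid plexus markers (median 0.23, adjusted p = 0.0344), with the potassium channel subunit Kcne2 at 0.24 ± 0.08 and the transporter Ttr at 1.42 ± 1.35. All 6 lists had an adjusted p = 0.869 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. The AMPA receptor partner Cacng2 was at -0.41 ± 0.14, and camera did not place the glutamatergic postsynapse apart; its median of 0.04 turned to -0.07 with quantile scaling over the 20 arrays. Mimic 5 carried the choroid plexus signal in both fractions: Ttr was at 13.51 in synaptoneurosome mimic 5 against a mean of 6.04 in the other 4 mimic arrays, and at 13.08 against 6.03 in homogenate.

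Without the 3 arrays that stood apart, oxidative phosphorylation (median -0.14, adjusted p = 0.001), ribosomal proteins (-0.23, 3.92e-12) and mural markers (-0.20, 0.023) kept their calls. The GABAergic list (-0.11, 0.193) and the microRNA machinery (-0.01, 0.799) did not, and the choroid plexus list turned to the other direction (-0.06, 0.962). With no filter on dim genes the microRNA machinery was at 0.0685.

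The count of 0 genes came from limma, with 542 genes at an unadjusted p below 0.05, and every alternative fit also gave 0. A share of 0.05 of the tested genes is 773, and random regroupings of the synaptoneurosome arrays gave a median of 714. The count of 542 rose to 2340 without mimic 5, 1216 without control 3 and 960 without control 1, and was 361 without mimic 3. Leaving out mimic 5 leaves arrays that stood apart in the control group only. When the synaptoneurosome arrays were regrouped, the median count was 5338 with the 3 arrays that stood apart in 1 group and 579.5 otherwise. The rise to 2340 therefore cannot be told apart from this structure of the arrays.

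Whether the mimic acted differently in the fractions was tested as the difference of both effects, and no gene passed (limma, smallest adjusted p = 0.998). An unadjusted p below 0.05 was reached by 243 genes. A share of 0.05 of the tested genes is 773, but random regroupings of the arrays gave a median of 205, so 243 is not below chance. The pseudogene Kmt5c-ps1 (0.37 ± 0.10) and Vasn (0.26 ± 0.09) had a higher effect in synaptoneurosomes, and Mt1f, a metallothionein gene, a lower one (-0.78 ± 0.21). Camera placed 7 lists apart. Oxidative phosphorylation genes had a lower effect in synaptoneurosomes (median -0.28, adjusted p = 1.28e-12), and so did ribosomal proteins (-0.15, 0.0172), interneuron markers (-0.32, 0.0172) and the GABAergic synapse (-0.35, 0.0195). Microglial markers (-0.23, 0.0318) and neuromodulator receptors (-0.24, 0.0464) were also lower, and the microRNA machinery (0.10, 0.0464) was higher. All 7 had an adjusted p = 0.872 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Without the 3 arrays that stood apart, oxidative phosphorylation (median -0.23, adjusted p = 4.41e-09) and ribosomal proteins (-0.29, 9.98e-14) kept the call, the latter with a larger median, and the other 5 did not (0.349 to 0.737). Those 5 medians were -0.07 for interneurons, -0.12 for the GABAergic synapse, -0.11 for microglia, -0.08 for neuromodulator receptors and 0.01 for the microRNA machinery. With no filter on dim genes the microRNA machinery was at 0.224. The count of 243 was 742 without synaptoneurosome mimic 5, 567, 443 and 433 without synaptoneurosome control 3, 4 and 1, 143 without homogenate mimic 4 and 140 without synaptoneurosome control 5. Leaving out mimic 5 again leaves arrays that stood apart among the controls only.

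The fractions themselves differed widely, and vascular transcripts were among the largest falls in synaptoneurosomes. Rgs5, a regulator of G protein signalling typical of pericytes, was lower by a log2 difference of -4.54 ± 0.26 in control rats and -4.59 ± 0.26 in mimic rats (limma adjusted p = 7.62e-10 and 5.89e-10). The endothelial receptor Adgrf5 was at -3.99 ± 0.12 and -4.00 ± 0.12, and the VEGF receptor Flt1 at -3.50 ± 0.09 and -3.54 ± 0.09 (adjusted p = 3.1e-15 and 2.51e-15). The other probe set of Flt1 gave -0.86 and -0.72. The small nucleolar RNAs Snord22 (-4.81 ± 0.41 and -4.12 ± 0.41) and Snord33 (-3.41 ± 0.43 and -2.60 ± 0.43), RNAs that reside in the nucleolus, fell as well. So did Rsrp1, an arginine and serine rich protein gene (-2.70 ± 0.25 and -2.64 ± 0.25), and Wsb1, a substrate receptor of a ubiquitin ligase (-2.61 ± 0.31 and -2.33 ± 0.31).

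The largest rises were those of Lrp1b, Pgap1 and Sema3e in both treatments. Lrp1b, a receptor of the LDL receptor family, was higher in synaptoneurosomes by 2.15 ± 0.19 in control rats and 2.35 ± 0.19 in mimic rats (limma adjusted p = 2.6e-07 and 6.78e-08). Pgap1, an enzyme that remodels GPI anchors, rose by 2.16 ± 0.17 and 2.08 ± 0.17. Sema3e, a secreted guidance cue, rose by 2.17 ± 0.23 and 2.02 ± 0.23, while its other probe set gave 0.01 and 0.17. Tenm1, a teneurin adhesion protein, rose by 1.86 ± 0.18 and 1.89 ± 0.18, and Dio2, which makes active thyroid hormone, by 1.83 ± 0.23 and 1.76 ± 0.23. Htr2c rose by 1.76 ± 0.27 and 1.55 ± 0.27. The adhesion proteins Fat3 (1.71 ± 0.12) and Chl1 (1.70 ± 0.13) and the guidance cue Slit2 (1.66 ± 0.21), named in mimic rats, were at 1.52 ± 0.12, 1.67 ± 0.13 and 1.72 ± 0.21 in control rats.

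In all, 6150 genes passed in control rats, 1818 higher and 4332 lower in synaptoneurosomes, and 6453 in mimic rats, 1697 higher and 4756 lower. At least a 2-fold difference was reached by 519 of these genes in control rats (313 higher, 206 lower) and 567 in mimic rats (198 higher, 369 lower). Both treatments shared 1146 higher and 3808 lower genes, where independent lists of these sizes would share 199 and 1332, and 0 genes passed in opposite directions. The differences correlated with r = 0.911 across genes, which are not independent replicates. The higher share of calls was 29.6% in control and 26.3% in mimic rats. It was 49.5% and 41.4% with quantile scaling over the 20 arrays, 23% and 15.7% with each array's median set to 0, and 43.1% and 45.9% with no filter on dim genes.

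**Figure D3:**
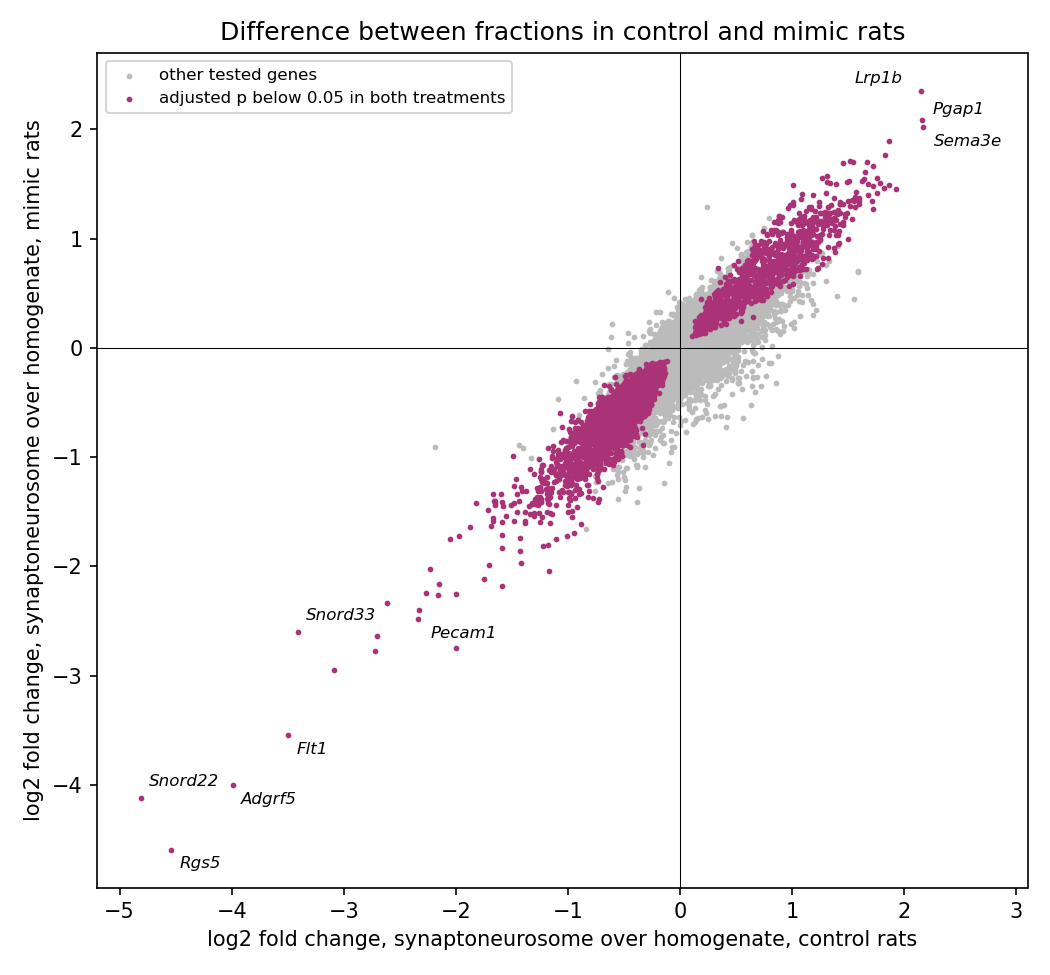
Log2 fold change of synaptoneurosome over homogenate in control rats (horizontal) against mimic rats (vertical), each point 1 of 15465 tested genes from 5 arrays per group, coloured where the adjusted p is below 0.05 in both. Vascular genes and small nucleolar RNAs lie at the lower left (Rgs5 at -4.54 and -4.59) and Lrp1b at the upper right (2.15 and 2.35).

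Among cell type markers, endothelial genes fell together: 13 of 14 fell in each treatment, over all genes and adjusted over the list alone. The adhesion molecule Pecam1 fell by 2.34 ± 0.12 in control rats and was at -2.48 ± 0.12 in mimic rats, and the efflux pump Abcb1a was at -2.33 ± 0.12 and -2.40 ± 0.12. The median was -1.50 in control and -1.69 in mimic rats (camera adjusted p = 7.01e-11 and 5.47e-11). The adjusted p = 0.0993 and 0.0958 with an estimated correlation, and the exact permutation test gave its smallest possible p = 0.00794 in both. Of 20 mural and fibroblast markers 7 fell and 2 rose in control rats, and 6 fell and 2 rose in mimic rats (12 fell and 2 rose with a replicate block), with the same counts adjusted over the list alone. The pericyte channel subunit Abcc9 was at -1.12 ± 0.07 in both, the smooth muscle actin Acta2 at -1.07 ± 0.24 and -1.12 ± 0.24, and Pdgfrb at -0.49 ± 0.11 and -0.54 ± 0.11. Camera did not place this list apart (adjusted p = 0.442 and 0.33), while the exact permutation test of scores per array gave an adjusted p = 0.399 and 0.0205.

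Of 16 astrocyte markers 9 rose in each treatment (10 in control and 9 in mimic rats adjusted over the list alone) and 0 fell. The glutamate transporters Slc1a3 (0.82 ± 0.13 in control and 0.59 ± 0.13 in mimic rats) and Slc1a2 (0.42 ± 0.07 and 0.46 ± 0.07) were among them. The list medians were 0.47 and 0.31 (camera adjusted p = 2.92e-05 and 0.000904), with an adjusted p = 0.397 and 0.666 with an estimated correlation, and 0.0352 and 0.0205 by the exact permutation test of scores per array. Microglial markers rose in 9 of 18 cases in control rats and 5 in mimic rats (9 and 4 adjusted over the list alone, and 8 in mimic rats with a replicate block), including Aif1 (0.49 ± 0.07 and 0.36 ± 0.07), the phosphatase Ptprc (0.65 ± 0.12 and 0.47 ± 0.12) and the receptor Gpr34 (0.98 ± 0.22 and 0.70 ± 0.22). Their medians were 0.45 and 0.30 (adjusted p = 3.15e-05 and 0.0028), with an adjusted p = 0.559 and 0.689 with an estimated correlation and 0.0352 and 0.0655 by the exact test. In mimic rats it was 0.0546 with no filter on dim genes.

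Oligodendrocyte precursor markers rose in 4 of 12 cases in control and 3 in mimic rats and 1 fell in each, with the same counts adjusted over the list alone. The proteoglycan Vcan was at 0.79 ± 0.18 and 0.84 ± 0.18, Bcas1 at 1.02 ± 0.29 and 1.17 ± 0.29, and the transcription factor Olig2 at -0.39 ± 0.12 and -0.40 ± 0.12. Camera placed the list above other genes in control rats (adjusted p = 0.0222, 0.0518 with a replicate block, 0.11 with no filter on dim genes and 0.137 without the 3 arrays that stood apart) and not in mimic rats (0.0923). The adjusted p = 0.559 in control rats with an estimated correlation, and it was 0.0352 and 0.0205 by the exact permutation test of scores. Camera did not place myelin genes apart (adjusted p = 0.821 and 0.944): 1 of 18 oligodendrocyte markers rose and 3 fell in control rats, and 0 rose and 4 fell in mimic rats, with the same counts adjusted over the list alone. With a replicate block 2 rose and 5 fell in control and 0 rose and 7 fell in mimic rats. Mog was at -0.82 ± 0.28 and -1.04 ± 0.28. The list's medians of -0.11 and -0.18 turned to 0.01 and 0.02 with quantile scaling over the 20 arrays and were -0.20 and -0.32 without the 3 arrays that stood apart.

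**Figure D4:**
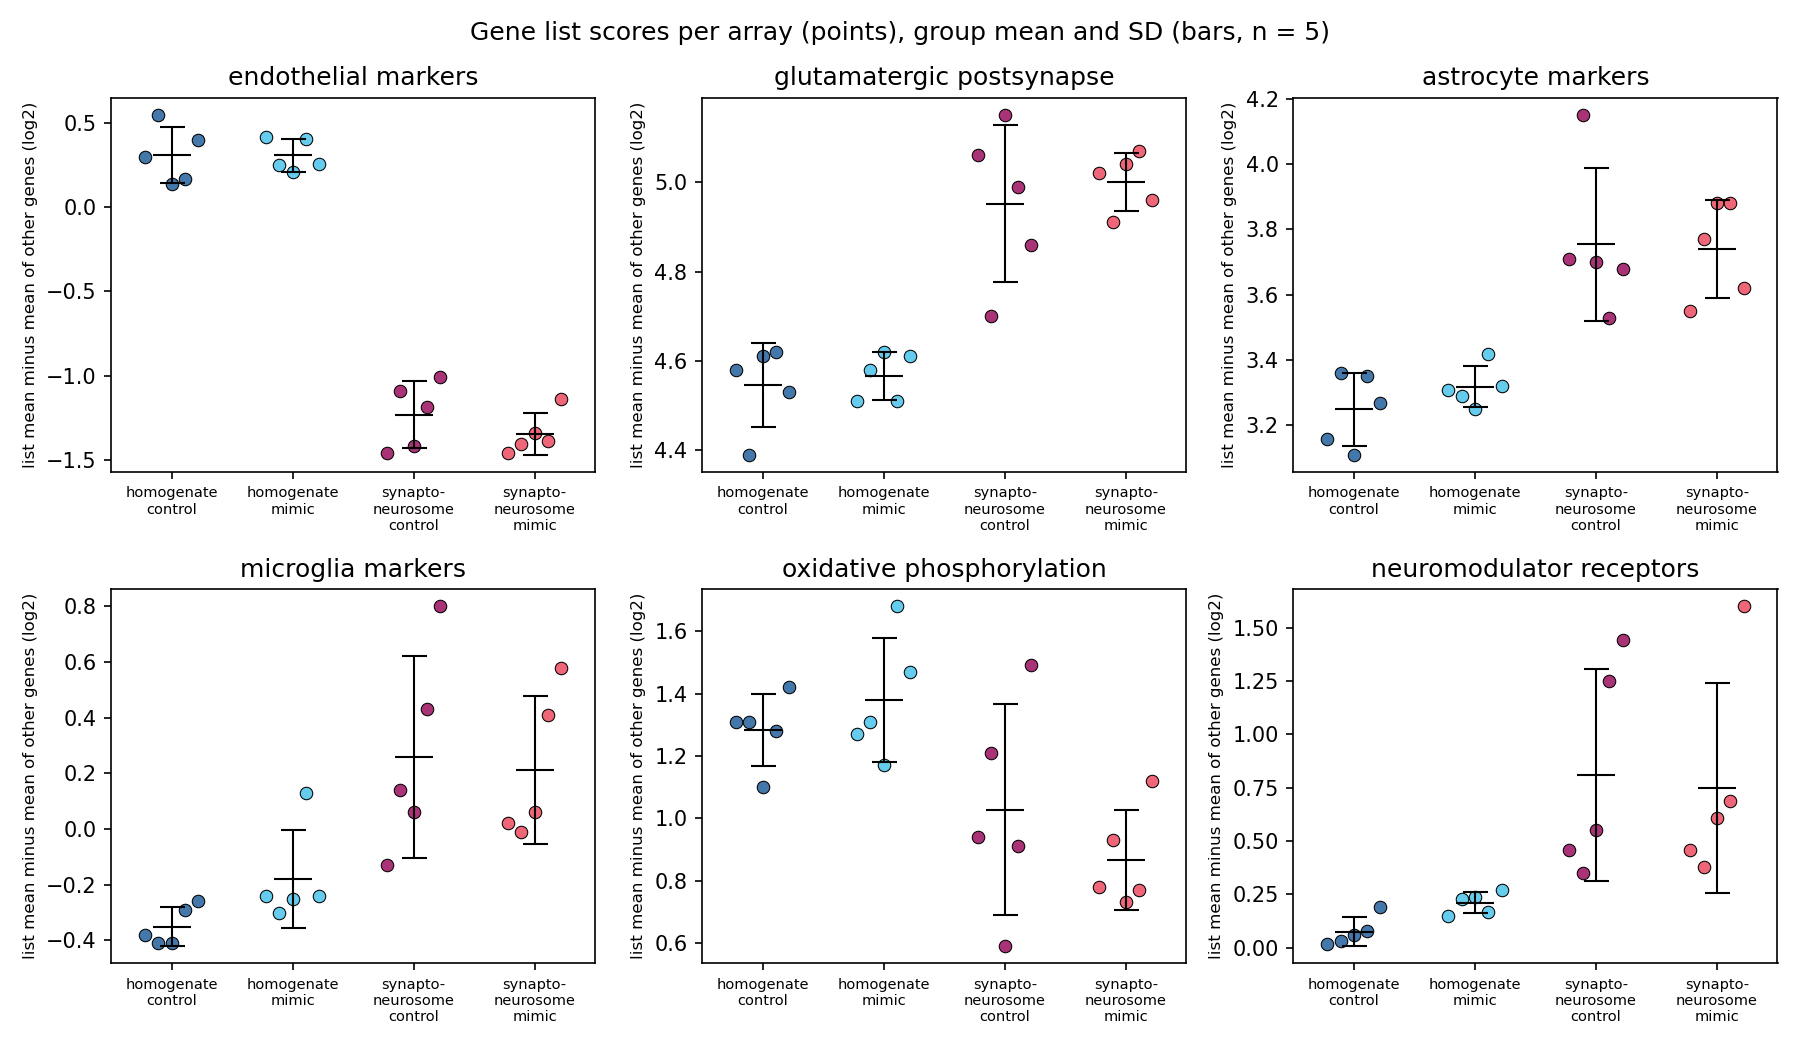
Mean log2 value of 6 gene lists minus that of all other tested genes, for each array (points) in the 4 groups, with group mean and SD (bars, 5 arrays per group). Endothelial scores do not overlap between fractions, and the 3 highest neuromodulator receptor scores, up to 1.60, belong to the 3 synaptoneurosome arrays that stood apart.

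Transcripts of the glutamatergic postsynapse lay above other genes in synaptoneurosomes: 16 of 35 rose and 4 fell in control rats (18 and 5 adjusted over the list alone), and 11 rose and 4 fell in mimic rats (13 and 4). The NMDA receptor subunits Grin2a (1.11 ± 0.14 in control and 1.18 ± 0.14 in mimic rats) and Grin2b (0.75 ± 0.12 and 0.74 ± 0.12) and the AMPA receptor subunit Gria3 (1.15 ± 0.17 and 0.97 ± 0.17) were higher. Nrgn, which encodes the small calmodulin-binding protein neurogranin, was lower (-1.43 ± 0.13 and -1.86 ± 0.13). The medians were 0.44 and 0.43 (camera adjusted p = 0.000665 and 0.000574), with an adjusted p = 0.397 and 0.356 with an estimated correlation and 0.0352 and 0.0205 by the exact permutation test of scores. In mimic rats 18 rose without the 3 arrays that stood apart. In mimic rats the adjusted p was 0.0546 with no filter on dim genes.

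Neuromodulator receptors rose in 12 of 35 cases in control and 8 in mimic rats, with 0 falls and the same counts adjusted over the list alone. The neuropeptide Y receptor Npy1r was at 1.42 ± 0.22 and 1.07 ± 0.22 and the opioid receptor Oprm1 at 0.70 ± 0.16 and 0.58 ± 0.16. The medians were 0.62 and 0.34 (camera adjusted p = 6.72e-08 and 3.21e-05), with an adjusted p = 0.677 and 0.69 with an estimated correlation and 0.0352 and 0.0205 by the exact permutation test of scores. The 3 arrays that stood apart had the 3 highest scores on this list, up to 1.60, against 0.35 to 0.69 in the other synaptoneurosome arrays. Without them the medians were 0.19 and 0.06 (adjusted p = 0.000638 and 0.00521).

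At the GABAergic synapse, 6 of 15 genes rose and 1 fell in control rats, and 3 rose and 3 fell in mimic rats, with the same counts adjusted over the list alone. The receptor subunits Gabra2 (1.06 ± 0.19 and 0.74 ± 0.19) and Gabrg1 (0.97 ± 0.14 and 0.57 ± 0.14) and the adhesion protein Nlgn2 (0.89 ± 0.19 and 0.96 ± 0.19) were higher, and the scaffold Gphn lower (-0.63 ± 0.12 and -0.79 ± 0.12). Camera placed the list above other genes in control rats (median 0.50, adjusted p = 0.00835, and 0.754 with an estimated correlation), but not without the 3 arrays that stood apart (0.315) or with no filter on dim genes (0.0584). In mimic rats the median was 0.27 (adjusted p = 0.109). The exact permutation test of scores gave an adjusted p = 0.0493 and 0.28. With a replicate block 6 rose and 3 fell in mimic rats, and without the 3 arrays that stood apart 6 rose and 4 fell in control rats and 4 rose and 5 fell in mimic rats (medians 0.23 and 0.13).

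Presynaptic vesicle genes went both ways: 11 of 36 rose and 12 fell in control rats, and 8 rose and 11 fell in mimic rats, with the same counts adjusted over the list alone. The synuclein Sncb (-1.26 ± 0.12 and -1.51 ± 0.12), the complexin Cplx1 (-1.18 ± 0.11 and -1.28 ± 0.11) and Syn1 (-0.86 ± 0.10 and -0.95 ± 0.10) fell, and the calcium channel Cacna1a rose (0.99 ± 0.12 and 1.14 ± 0.12). Camera did not place the list apart (adjusted p = 0.447 and 0.63), and its median of 0.09 in mimic rats was -0.03 with quantile scaling within each fraction. The medians of 0.14 in control and 0.09 in mimic rats turned to -0.02 and -0.09 without the 3 arrays that stood apart. Dendritically localised mRNAs rose in 10 of 30 cases and fell in 6 in control rats (10 and 7 adjusted over the list alone), and rose in 12 and fell in 6 in mimic rats (14 and 6). In control rats 5 rose and 5 fell with a replicate block, and 19 rose and 5 fell without the 3 arrays that stood apart. Arc, whose mRNA travels into dendrites, rose by 1.06 ± 0.28 and 1.23 ± 0.28. The list did not pass (adjusted p = 0.179 and 0.0518), but it passed without the 3 arrays that stood apart (0.000215 and 0.000373). With all arrays and an estimated correlation its adjusted p was 0.784 and 0.748.

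Nuclear-encoded genes of oxidative phosphorylation fell in 27 of 66 cases with 1 rise in control rats, and in 50 with 0 rises in mimic rats (27 and 53 falls adjusted over the list alone). Ndufa5 was at -0.65 ± 0.09 and -0.66 ± 0.09, the ATP synthase subunit Atp5f1b at -0.60 ± 0.11 and -0.70 ± 0.11, and Sdhb of complex II at -0.43 ± 0.10 and -0.65 ± 0.10. The medians were -0.34 and -0.64 (camera adjusted p = 0.0157 and 2.24e-07), with an adjusted p = 0.784 and 0.69 with an estimated correlation. In control rats the adjusted p was 0.0623 with a replicate block, and the exact permutation test of scores gave 0.246 in control and 0.0205 in mimic rats. Without the 3 arrays that stood apart 39 fell in control rats (median -0.5, camera adjusted p = 5.33e-05) and 58 in mimic rats (median -0.68, camera adjusted p = 4.64e-09). Of 71 ribosomal protein genes 4 rose and 1 fell in control rats, and 1 rose and 2 fell in mimic rats (0 in each direction adjusted over the list alone). In mimic rats 1 rose and 6 fell with a replicate block. Without the 3 arrays that stood apart 21 rose and 0 fell in control rats (median 0.29, adjusted p = 3.08e-06), and 5 rose and 4 fell in mimic rats (median -0.03). Rplp0 of the ribosomal stalk was at 0.70 ± 0.19 and 0.64 ± 0.19. Camera placed them above other genes in control rats (median 0.12, adjusted p = 0.019, and 0.802 with an estimated correlation), though not with no filter on dim genes (0.366), and not in mimic rats (median -0.08, adjusted p = 0.371). By the exact test the adjusted p was 0.533 and 0.832. With quantile scaling over the 20 arrays the median in mimic rats was 0.05.

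Markers of excitatory neurons fell in 6 of 11 cases and rose in 1 in each treatment, with the same counts adjusted over the list alone, among them the transcription factors Neurod6 (-1.34 ± 0.22 and -1.52 ± 0.22) and Neurod2 (-0.82 ± 0.16 and -0.83 ± 0.16). The medians were -0.40 and -0.51 (camera adjusted p = 0.141 and 0.0923). The exact permutation test of their scores gave p = 0.0159 and 0.00794, adjusted to 0.0493 and 0.0205. In control rats 7 fell and 0 rose with a replicate block. Immediate early genes fell in 5 of 22 cases and rose in 1 in control rats (11 and 1 with a replicate block, 9 and 1 without the 3 arrays that stood apart), and fell in 7 and rose in 1 in mimic rats, with the same counts adjusted over the list alone. The transcription factors Jun (-1.21 ± 0.17 and -1.24 ± 0.17) and Egr1 (-0.96 ± 0.24 and -1.24 ± 0.24) fell (list adjusted p = 0.256 and 0.443). Of the 58 described miR-17 targets 6 rose and 18 fell in control rats, and 7 rose and 20 fell in mimic rats, with the same counts adjusted over the list alone. Of these targets, 11 rose and 14 fell in control and 11 rose and 19 fell in mimic rats without the 3 arrays that stood apart. Atg16l1 of the autophagy pathway (-0.83 ± 0.08 and -0.87 ± 0.08), the helicase Ddx5 (-1.03 ± 0.11 and -1.16 ± 0.11) and the autophagy receptor Sqstm1 (-0.92 ± 0.12 and -1.11 ± 0.12) fell. Rgs5 belongs to this list too, and camera did not place it apart (adjusted p = 0.228 and 0.726).

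Leukocyte markers lay above other genes in both treatments (camera adjusted p = 0.0389 and 0.0266, and 0.559 and 0.666 with an estimated correlation), with 1 of 10 rising in control and 5 in mimic rats, 0 falling, and the same counts adjusted over the list alone. With a replicate block the adjusted p was 0.0883 and 0.0539, and without the 3 arrays that stood apart 0.315 and 0.0955. It was 0.0493 and 0.0205 by the exact permutation test of scores, and with a replicate block 3 rose in mimic rats. Interferon response genes passed in mimic rats (median 0.05, adjusted p = 0.0363, and 0.689 with an estimated correlation) with 1 of 26 rising and 1 falling, and 0 adjusted over the list alone. They did not pass with a replicate block (0.0556), with no filter on dim genes (0.409) or by the exact permutation test (0.0769), and the median was -0.02 with each array's median set to 0. In control rats 5 rose and 1 fell (1 and 1 adjusted over the list alone, list adjusted p = 0.141). The counts were 3 rises and 2 falls in control and 2 rises and 1 fall in mimic rats with a replicate block. Leukocyte and interferon lists were dim: their scores averaged -2.08 and -1.74 in homogenate control and -1.84 and -1.65 in synaptoneurosome control. The median difference of all genes was -0.14 in control and -0.18 in mimic rats without the lowest 50% by mean. It was 0.05 in both with no filter on dim genes, where leukocyte markers kept their call (0.0151 and 0.00958). Whether either list rose more than equally dim genes was not tested. Innate inflammation genes rose in 4 of 21 cases in both and fell in 3 in control and 2 in mimic rats (4 and 3, then 3 and 2, adjusted over the list alone). The prostaglandin synthase Ptgs2 was at 1.60 ± 0.27 and 1.32 ± 0.27 and the adhesion molecule Vcam1 at 0.81 ± 0.13 and 0.68 ± 0.13 (list adjusted p = 0.12 and 0.0993 by camera, and 0.0352 and 0.0205 by the exact permutation test).

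Interneuron markers rose in 5 of 20 cases and fell in 2 in control rats, and rose in 3 and fell in 7 in mimic rats, with the same counts adjusted over the list alone. Reln, a secreted glycoprotein (1.39 ± 0.25 and 1.24 ± 0.25), and Ndnf (1.55 ± 0.31 and 1.34 ± 0.31) rose (list adjusted p = 0.191 and 0.823). In control rats 3 rose and 7 fell without the 3 arrays that stood apart, and the list's median there turned from 0.28 to -0.29. Of 10 dentate granule markers 1 rose and 4 fell in control rats and 1 rose and 3 fell in mimic rats, with the same counts adjusted over the list alone. Among them were Stxbp6 (-0.62 ± 0.07 and -0.67 ± 0.07, and -0.38 and -0.37 by its other probe set) and the calcium buffer Calb1 (-0.92 ± 0.34 and -1.46 ± 0.34). CA3 and CA2 markers rose in 1 of 13 cases and fell in 5 in each treatment (4 and 5 in control and 2 and 6 in mimic rats with a replicate block), with the same counts adjusted over the list alone, with Pcp4 at -1.59 ± 0.45 and -2.18 ± 0.45 (-0.49 and -0.74 by its other probe set). Of 8 CA1 markers 1 rose and 1 fell in control rats, and 0 rose and 1 fell in mimic rats, with the same counts adjusted over the list alone. For CA1 markers a replicate block gave 5 rises and 1 fall in control and 2 rises and 1 fall in mimic rats. Of 15 extrahippocampal neuron markers 1 rose in each treatment, Rspo2 (1.49 ± 0.19 and 1.52 ± 0.19), and 1 and 2 fell (0 and 1 adjusted over the list alone). With a replicate block 2 rose in each and 2 and 4 fell. Camera placed none of these lists apart, with adjusted p from 0.12 to 0.995, and extrahippocampal markers in mimic rats alone passed the exact permutation test of scores (adjusted p = 0.0205).

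Stress and glucocorticoid genes rose in 3 of 20 cases and fell in 4 in control rats (4 and 8 adjusted over the list alone), and rose in 1 and fell in 4 in mimic rats, with the same counts adjusted over the list alone. The microRNA machinery had 0 rises and 4 falls of 16 in each treatment (1 and 2 falls adjusted over the list alone). Reactive astrocyte genes rose in 1 of 18 cases and fell in 2 in control rats (0 and 1 adjusted over the list alone), and rose in 2 and fell in 3 in mimic rats, with the same counts adjusted over the list alone. Cell cycle genes rose in 2 of 12 cases and fell in 0 in control rats (1 and 0 adjusted over the list alone), and rose in 2 and fell in 1 in mimic rats. Of 12 choroid plexus markers 1 fell in control rats and 0 changed in mimic rats, and 0 passed adjusted over the list alone. Of 7 ependymal markers 0 changed, and of 6 blood markers 0 changed in control rats and 1 rose in mimic rats, with 0 adjusted over the list alone. Camera placed none of these lists apart, with adjusted p from 0.109 to 0.958, and stress genes in mimic rats alone passed the exact permutation test of scores (adjusted p = 0.0205). With a replicate block 3 stress genes rose and 8 fell in control and 1 rose and 8 fell in mimic rats, and the microRNA machinery had 1 rise and 2 falls in mimic rats. Reactive astrocyte genes then rose in 3 and fell in 3 cases in control and rose in 4 and fell in 3 in mimic rats, 1 cell cycle gene rose in each, and 3 choroid plexus markers rose in control and 2 in mimic rats with 0 falls. In the same fit 1 ependymal marker fell in control rats, and 1 blood marker rose in control and 1 fell in mimic rats.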

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

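Except for the splits of the arrays between fractions, the tests of explanations in this part concern patterns that were found in the data. The prediction for transcripts made at the endoplasmic reticulum was written before its own test, but for arrays already seen to stand apart. The rest of these tests were chosen only after the results were seen.

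Scores of gene lists were checked in 124 groups of 5 arrays, and 15 groups held an array far from the other 4, where 6.2 would by chance, since about 1 in 20 groups would hold such an array with no cause. In synaptoneurosome mimic rats the array was replicate 5 in 7 cases. It scored 6.01 on the GABAergic synapse (others 5.05 to 5.29), 4.86 on dendritic mRNAs (5.31 to 5.42), 1.60 on neuromodulator receptors (0.38 to 0.69), 1.41 on dentate granule markers (1.04 to 1.14), 1.38 on CA3 and CA2 markers (0.91 to 0.95), 1.74 on interneuron markers (0.65 to 0.85) and 0.11 on choroid plexus markers (-1.87 to -1.83). Homogenate mimic 5 scored -0.22 on choroid plexus markers (-2.13 to -1.96). Homogenate mimic 4 scored -1.20 on reactive astrocyte genes (-1.56 to -1.47) and 0.13 on microglial markers (-0.30 to -0.24). Homogenate control 2 scored 0.07 on stress genes (0.20 to 0.24) and 0.09 on extrahippocampal neurons (-0.52 to -0.37). Synaptoneurosome control 2 scored -0.96 on immediate early genes (-0.70 to -0.60) and 3.73 on excitatory neurons (4.07 to 4.16), and synaptoneurosome control 1 scored 1.45 on oligodendrocytes (2.06 to 2.29).

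Among the genes named in the text, 24 of 412 groups held such an array, against 20.6 by chance. In synaptoneurosome mimic 5 these were the log2 values of Gabrd (7.56), Ndufa3 (7.04), Ttr (13.51), Snord33 (14.79), Wsb1 (6.87), Srsf5 (9.25) and Psmd8 (8.41), and in homogenate mimic 5 Ttr (13.08), Rsrp1 (10.23), Srsf5 (10.81) and Hspa5 (13.10). In homogenate mimic 4 they were Cd68 (6.61) and Snord33 (18.51), and in synaptoneurosome mimic 4 Nrgn (15.08) and Mt1f (5.73). In synaptoneurosome control 3 they were Mir299 (5.37), Pecam1 (6.40) and Neurod2 (11.20), in homogenate control 3 Flt1 (9.38) and Atg16l1 (10.09), and in synaptoneurosome mimic 3 Acta2 (6.14). The others were Vasn in homogenate control 2 (5.46), Egr1 in homogenate control 1 (10.48) and Mog in synaptoneurosome control 1 (8.41).

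Synaptoneurosome control 4, control 5 and mimic 5 stood apart from the other synaptoneurosome arrays. Carry-over of whole-tissue RNA would leave genes between the level of the other synaptoneurosome arrays and that of homogenate, but of the genes displaced by over 1 on the log2 scale (970, 1476 and 1279) 80.5%, 85.8% and 89.8% lay over 0.5 outside that range; this test replaced one on correlations (r = 0.213, 0.191 and 0.159 across genes) that did not decide, and the other 7 arrays gave 50% to 100% of far fewer genes. A difference between the animals' tissue would show in the homogenate of equal number, if equal numbers mark the same animal, which the labels do not say. There the slope on the same genes was 0.085, 0.137 and 0.0852 (SD 0.03), with r = 0.233, 0.345 and 0.216 across genes. The other 7 arrays had slopes from 0.1 to 0.557. Carry-over is therefore argued against as the whole cause, and the animals' tissue only if equal numbers mark the same animal. More mRNA of proteins made at the endoplasmic reticulum may account for part of it and stays open: its median displacement exceeded that of cytosolic proteins by 0.56, 0.49 and 0.80, but 2 of the other 7 arrays, control 3 at 0.65 and mimic 4 at 0.54, lay above the lowest of these, and the lowest of the other 7 was -0.43. Apart from the animals' tissue and mRNA made into protein at the endoplasmic reticulum, no biological explanation was tested. The labels give no difference between these arrays and the rest. Replicate 5, the number of control 5 and mimic 5, had the lowest mean log2 value in each of the 4 groups. These means were 6.217 and 6.21 in homogenate control and mimic, and 6.177 and 6.19 in synaptoneurosome control and mimic. Homogenate control 5 and mimic 5 had the highest component scores in homogenate, 5.6 and 3.7. Differences in RNA quality or processing were not tested and stay open.

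Choroid plexus markers were high in mimic 5 in both fractions. All 12 tested markers had their highest mimic value in replicate 5 in homogenate and in synaptoneurosomes. Ttr reached 13.08 against a mean of 6.03 in homogenate and 13.51 against 6.04 in synaptoneurosomes, and Enpp2, which the oligodendrocyte list also holds, 14.60 against 12.09 and 15.38 against 11.72. Choroid plexus in the dissected tissue of 1 animal is a candidate explanation that these values fit. The markers counted are members of the list whose score flagged mimic 5, so their count is not separate support. A response of that animal's own tissue to the mimic was not tested.

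The mimic effect differed between fractions for 7 lists by camera, with adjusted p of 1.28e-12 for oxidative phosphorylation, 0.0172 for ribosomal proteins and interneurons, 0.0195 for the GABAergic synapse, 0.0318 for microglia, and 0.0464 for neuromodulator receptors and the microRNA machinery. None of the 7 passed with an estimated correlation (adjusted p = 0.872). Within synaptoneurosomes, the unequal split of the 3 arrays that stood apart (2 in control, 1 in mimic) may have moved lists: 3 of the 7 lists called there kept their call and direction without these arrays. The medians of these 3 were -0.17 with all arrays and -0.14 without the 3 for oxidative phosphorylation, -0.10 and -0.23 for ribosomal proteins and -0.24 and -0.20 for mural markers. For these 3 calls that argues against the split as the cause, while for the other 4 lists it stays open. Over all 7 lists the rule set for this test, on the share that kept their call, was met in neither direction. No list passed in synaptoneurosomes with an estimated correlation or by the exact test of scores per array, so a shift of these lists by the mimic was not shown, and the higher mural scores of the controls lay in control 2 and control 5.

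Of 126 possible splits of the arrays compared, 100 were drawn, the real one included. The real count of 0 genes for the mimic in homogenate (highest other 0), in synaptoneurosomes (highest other 3795) and for the difference between fractions (highest other 0) is met by all 100 splits whatever the data, so these counts test nothing. At an unadjusted p below 0.05 chance cannot be excluded: 40 splits gave at least the real 268 genes in homogenate (highest other 618), 65 at least 542 in synaptoneurosomes (highest other 5832) and 42 at least 243 for the difference between fractions (highest other 3321). The high counts point to a structure of the samples: in synaptoneurosomes, 18 splits that put the 3 arrays that stood apart in 1 group gave 0 to 3795 genes, and the other 82 gave 0 to 1. For the fraction comparisons only the real split, 1 of 100, gave as many genes. The counts were 6150 in control rats (highest other 1131) and 6453 in mimic rats (highest other 895). If equal numbers are pairs, only the 16 splits that part all number pairs apply. Among these the highest other count was 0 in both, and 1 of 16, the real one, gave as many. With 16 splits this share cannot fall below 0.05, so chance cannot be excluded at that level if the arrays are paired.

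Probe sets without a single gene symbol, which the comparisons leave out, also differed between fractions: 6040 in control rats and 5434 in mimic rats of 29357 tested, with 0 in the mimic comparisons.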

How the results depend on the processing

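Leaving out 3 arrays and the scores per array were chosen only after the results were seen. In every setting with an adjusted p, 0 genes passed for mimic against control in either fraction or for the difference between fractions, including leaving out each array in turn (0 to 0). The fraction comparisons gave 4890 to 7628 genes in control rats and 5010 to 8961 in mimic rats over the settings with 1 value per gene, 5428 to 6252 and 5652 to 6350 leaving out each array in turn, and 0 calls turned in direction. An unadjusted p below 0.05 with a fold of at least 1.5 gave 8 genes in homogenate (7 higher), 30 in synaptoneurosomes (6 higher), 24 for the difference between fractions (2 higher), 2227 between fractions in control rats and 2397 in mimic rats. All probe sets gave 12061 and 12111 with more features tested; the cause of these changes was not tested.

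With an estimated correlation 0 lists passed in each of the 5 comparisons. Leaving out the 3 arrays that stood apart left 4 lists in synaptoneurosomes (1 higher, 3 lower; 3 shared with all arrays) and 3 for the difference between fractions (2 shared). Lists called only without these arrays were neuromodulator receptors in homogenate (adjusted p = 0.00319), microglia in synaptoneurosomes (0.0466), astrocytes for the difference between fractions (0.0147) and dendritic mRNAs between fractions. With no filter on dim genes 9 lists passed between fractions in control rats (7 shared) and 7 in mimic rats (5 shared). The choroid plexus list turned in direction in synaptoneurosomes (adjusted p = 0.962), where mimic 5 was among the arrays removed. Scores per array gave 0 lists for the mimic in homogenate and 0 in synaptoneurosomes, 10 between fractions in control rats (8 shared with camera) and 12 in mimic rats (6 shared). The miR-17 target score differed by -0.02 to 0.00 in homogenate and by 0.02 to 0.13 in synaptoneurosomes leaving out each array in turn. Without the 3 arrays, counts of list members other than those in the report that moved by over 1.5 times did so by at most 4 genes. Counted over all settings, genes examined by name lost their call between fractions in 136 cases in control and 127 in mimic rats and gained a call in 47 and 40. Fmr1 alone turned in direction, in mimic rats with quantile scaling over 20 arrays (0.01, adjusted p = 0.906, against -0.17); the cause was not tested.

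With the replicate number as a block, 0 genes passed for the mimic in either fraction or for the difference. Across treatments the numbers were not taken to pair the arrays, since not every pair had an r over 0.1 across genes. In homogenate r was 0.0204 to 0.411 (2 of 5 pairs over 0.1, 2 best with their own number). In synaptoneurosomes 4 pairs had r from 0.524 to 0.828, each best with its own number, which is a hint from the data and not the design, and pair 4 had -0.305. Between fractions the fixed block gave 5655 and 6388 genes (5175 and 5716 shared) and the random block 7145 and 7330. With paired sign flips the miR-17 target score differed by -0.01 in homogenate (exact p = 0.562) and 0.07 in synaptoneurosomes, where mimic lay above control in 5 of 5 pairs (exact p = 0.0625, the smallest possible). Of genes examined by name, the fixed block ended 6 and added 8 calls in control rats and ended 6 and added 7 in mimic rats, and the random block added 7 and 4. Counts of list members moved by over 1.5 times with the fixed block stand in the report. The random block moved falls of the microRNA machinery in control rats from 4 to 8 and rises of interferon genes in mimic rats from 1 to 4. The block changed no other list call than those given in the report. The seed-site alternatives (no matching, 8-mer alone, 7-mer alone) were not run, because 3′ untranslated sequences were not used here. Changes of genes left out as dim and of the unnamed probe sets were not named here, and 5 arrays per group leave small effects undetected.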

Other observations

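The gene families in this part and their tests were chosen only after the values of leading genes were seen. In 16 families tested, protocadherins, adhesion proteins of neurons, rose most evenly in synaptoneurosomes: 29 of 32 rose and 1 fell in control rats and 28 rose and 1 fell in mimic rats, with Pcdhb17 at 1.15 ± 0.12 and 1.12 ± 0.12. Their medians were 1.07 and 0.83 (camera adjusted p = 7.96e-15 and 4.58e-13, and adjusted p = 0.239 and 0.262 with an estimated correlation). Potassium channel subunits rose in 26 of 69 cases in control and 14 in mimic rats and fell in 5 and 3, with Kcnma1 at 0.96 ± 0.11 and 1.01 ± 0.11 (adjusted p = 4.16e-08 and 4.02e-06, and adjusted p = 0.325 and 0.304 with an estimated correlation). Their medians were 0.35 and 0.23 with all arrays and 0.16 and 0.08 without the 3 arrays that stood apart. In a list of proteins made at the endoplasmic reticulum 20 of 45 genes rose and 1 fell in control rats and 13 rose and 3 fell in mimic rats, with the chaperones Hspa5 (1.22 ± 0.18 and 1.15 ± 0.18) and Hsp90b1 (1.21 ± 0.15 and 0.97 ± 0.15) among them. The exact permutation test of its scores gave p = 0.00794 in control and 0.151 in mimic rats (adjusted to 0.0181 and 0.172), and the adjusted p = 0.34 and 0.44 with an estimated correlation. Much of this rise lay in the 3 arrays that stood apart: without them 14 rose and 4 fell in control rats and 13 rose and 14 fell in mimic rats, and the medians were 0.19 and -0.02 (camera adjusted p = 0.00134 and 0.135), against 0.61 and 0.24 with all arrays. Of 47 genes for cytosolic proteins 32 fell in control and 44 in mimic rats and 0 rose, with the adaptor Ywhaz at -0.63 ± 0.08 and -0.75 ± 0.08 (adjusted p = 0.34 and 0.304 with an estimated correlation).

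In each of the next 5 families more members fell than rose. Of 12 SR splicing factors 11 fell in each treatment, with Srsf2 at -1.44 ± 0.11 in control and -1.40 ± 0.11 in mimic rats and Srsf5 at -1.67 ± 0.18 and -1.56 ± 0.18 (camera adjusted p = 5.55e-07 and 2.16e-06, and adjusted p = 0.325 and 0.304 with an estimated correlation). Of 5 H/ACA small nucleolar RNAs 4 fell in each, with Snora58 at -1.08 ± 0.13 and -1.32 ± 0.13 (adjusted p = 0.00741 and 0.0158, and adjusted p = 0.239 and 0.262 with an estimated correlation). Proteasome subunits fell in 25 of 46 cases and rose in 1 in control rats and fell in 33 in mimic rats, with Psmd8 at -1.07 ± 0.08 and -1.08 ± 0.08 (adjusted p = 0.000485 and 8.09e-07, and adjusted p = 0.381 and 0.304 with an estimated correlation). Mitochondrial ribosomal proteins fell in 41 of 78 cases in control and 63 in mimic rats and rose in 0, with Mrpl17 at -0.99 ± 0.12 and -1.32 ± 0.12 (adjusted p = 1.72e-05 and 2.42e-10, and adjusted p = 0.381 and 0.304 with an estimated correlation). Zinc finger genes fell in 163 of 304 cases in control and 152 in mimic rats and rose in 3 and 4, or 17 and 18 without the 3 arrays that stood apart (all arrays, adjusted p = 5.08e-08 and 9.82e-06, and adjusted p = 0.325 and 0.339 with an estimated correlation). The medians of these families kept their sign with quantile scaling over the 20 arrays, and 0 members of any family passed in the mimic comparisons. Camera placed some families apart there, such as collagens below other genes in homogenate (adjusted p = 4.2e-05) and endoplasmic reticulum genes below them in synaptoneurosomes (median -0.28, adjusted p = 5.49e-07, and -0.15, adjusted p = 3.89e-05, without the 3 arrays that stood apart). None passed with an estimated correlation (smallest adjusted p = 0.323 and 0.593) or by the exact permutation test (smallest adjusted p = 0.254 and 0.804). The other 7 families were microRNA precursors, solute carriers, semaphorins, tubulins, proton pump subunits, collagens and adhesion G protein receptors, and with an estimated correlation none of the 16 passed between fractions (smallest adjusted p = 0.239 and 0.262).

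The effects of the mimic in both fractions correlated with r = 0.116 across genes, which are not independent replicates. Of 126 splits of the animals as numbered, 117 gave an r as high, with a median of 0.298 and a highest other value of 0.594.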
